A study of Mus musculus with 16 samples.

How the data were processed

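Total RNA from the distal 5 mm of the left femur of ovariectomized female C57BL/6 mice was labelled and hybridized to 16 Affymetrix mouse whole-genome arrays, 1 array per mouse, per the labels' protocols. The deposited values are linear signal intensities per probe set, made by the authors with GCOS, per the submitters' processing notes; the software version is not given in the sources used here. The 2% trimmed mean of the deposited intensities was 500 on each array, so they were used as deposited, without further normalization. Detection calls were not used here, and the authors' background steps are not given in the sources used here.

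The 4 groups of 4 mice were wild-type mice and mice lacking estrogen receptor alpha in osteoclasts, each with vehicle or estrogen given 4 hours before harvest. The labels of the knockout mice without estrogen do not name a vehicle, and their treatment was taken from the series design text, which also states that RNA was not pooled. The estrogen compound and dose are not given in the sources used here.

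Of 45101 probe sets, 64 were controls. The platform annotation listed genes for 35890 probe sets, with 1 symbol for 34958 and several for 932, and the other probe sets stayed unnamed. Symbols were checked against the RefSeq gene table through Entrez identifiers, which matched 34741 of the named probe sets. No genome coordinates are printed, since the intensities carry no build. Each of 18193 genes was represented by its probe set of highest mean, and the 30% of genes with the lowest mean were left out, which left 12735 genes with a mean signal above about 109. The unnamed probe sets, 10092 in number, were tested apart in the same way, and of 4371 above the same level 0 passed in any of the 7 comparisons by limma, with 136 to 274 at an unadjusted p under 0.05 per comparison.

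Signals were transformed as log2(signal + 16), so a fold on this scale understates the change of low genes. A linear model with 1 mean per group over all 16 arrays, with 12 residual degrees of freedom, was fitted with limma 3.58.1 in R 4.3.3, with an empirical Bayes variance trend. The contrasts were estrogen against vehicle in each genotype, knockout against wild type under each treatment, the difference between the estrogen responses (the interaction), and the averages of the estrogen and of the genotype differences. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. Fasl lay under the filter, so its limma values come from the fit without a filter. Esr1, Fasl, Fas and Ctsk were also compared by exact two-sided permutation of the mean log2 value over the 70 arrangements of 4 against 4 arrays, which cannot give a p under 0.0286, and by permutation within strata over 4900 arrangements for the genotype average and for the difference between responses. After the replicate sets (1 and 2, or 3 and 4) were seen to differ, the permutations were repeated within these sets, over 36 arrangements per pair of groups and 1296 for the averages and the difference between responses.

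The 23 gene lists were fixed before the data were examined, as were the main tests and the rule for named genes. Some tests were chosen later, after the data were seen. The rule allowed more members per list than the 2 named here. They covered osteoclast, osteoblast and osteocyte, cartilage, skeletal muscle, adipocyte, erythroid, neutrophil lineage, monocyte and macrophage, B lymphocyte, T lymphocyte and NK cell, megakaryocyte and endothelium genes. The others covered estrogen response, nuclear receptors and coregulators for steroids, Fas and apoptosis, cell cycle, immediate early, circadian clock, glucocorticoid response, heat shock, interferon response, inflammatory cytokines, and TGF-beta, BMP, Wnt and IGF signalling. Of 423 list members, 391 had a probe set and 357 were tested; members without a probe set are not named. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, with camera's estimated correlation and fry as alternatives. Members were also counted as passing when adjusted over the list alone.

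The genes named per comparison were the 10 largest rises and falls among genes that passed without overlap between the groups or, where fewer than 5 genes passed, the 5 of smallest p. Esr1, Fasl, Fas and Ctsk were named throughout, and so were the 2 members with the largest absolute change of each list that passed or held a passing member. Predicted genes without an approved symbol were counted and not named.

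The groups share replicate numbers, so the pairing was checked on the deviations of the arrays from their group means. All 24 correlations between arrays of the same number in different groups lay above the 0.1 set for pairing, between 0.178 and 0.593. Arrays of the other number in the same replicate set (1 and 2, or 3 and 4) correlated as much, with a median of 0.355 against 0.314, and 9 of 16 arrays correlated best with an array of their own number. The highest correlation between any 2 arrays was 0.979, and 0 pairs of arrays were identical.

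The procedure was tested on simulated data made from the spread of the real arrays. For estrogen in wild type over 12735 genes, 53 of 100 genes changed by 1 log2 unit and 95 of 100 changed by 2 log2 units were recovered, with 8 false calls, and 3 of 3 lists shifted by 0.5 were recovered with 0 others called. Fry also recovered 3 of 3 lists. The simulated noise was independent between genes and held no difference between the replicate sets. It therefore does not show how many false calls correlated genes or the replicate sets would give. Other settings chosen beforehand were pseudocounts of 1 and 64, quantile normalization, median scaling, no filter and a filter at the 50th percentile, array quality weights, no variance trend, fits to the compared arrays alone, every probe set in place of 1 per gene, the replicate number as a block, and each array left out in turn. Settings chosen after seeing the data were the replicate set (1 and 2, or 3 and 4) as a term in the fit (in addition, combined with every named probe set), each set alone, and the data without the 3 arrays of highest spike-in signal. In the estrogen comparisons and the interaction, the replicate number as a block paired vehicle and estrogen mice of the same number within a genotype. In the genotype comparisons the block was the replicate number over all groups. No label names such pairs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.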

Results

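Gene expression was measured in the distal 5 mm of the left femur of 16 ovariectomized female mice, with 1 microarray per mouse and no pooling of RNA. Mice were wild type or lacked estrogen receptor alpha in osteoclasts, the cells that resorb bone, and received vehicle or estrogen 4 hours before the bone was taken. Each of the 4 groups held 4 mice. The series names Fas ligand, a death receptor ligand, as its subject, so the comparisons ask which genes respond to estrogen in bone and whether the response needs the receptor in osteoclasts. The tissue was whole bone with its marrow, so a change within osteoclasts alone is diluted by every other cell. The 2% trimmed mean signal was 500 on each array and the median signal ran from 153 to 217, and the number of arrays limits the precision. Signals below are array signal intensities given as mean ± SD (n = 4), and log2 differences are on the log2(signal + 16) scale with their SE.

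Skeletal muscle genes separated the mice numbered 1 and 2 from the mice numbered 3 and 4 within every group. All 20 tested members of the skeletal muscle list were lower in replicates 3 and 4, with a median log2 difference of −4.04 (camera adjusted p = 1.1e-34; adjusted p = 0.140 with an estimated correlation). The adipocyte list was also lower there, with a median of −0.93 (adjusted p = 0.00416; adjusted p = 0.348 with an estimated correlation), and so were the erythroid (−0.37, adjusted p = 0.0026), glucocorticoid response (−0.43, adjusted p = 0.00593) and B lymphocyte lists (−0.39, adjusted p = 0.0155), which did not pass with an estimated correlation (adjusted p = 0.91, 0.769 and 0.91). The osteoclast list was higher in replicates 3 and 4 by a median of 0.58 (adjusted p = 2.42e-08; adjusted p = 0.144 with an estimated correlation), and the endothelium list by 0.43 (adjusted p = 0.000627; adjusted p = 0.207 with an estimated correlation). The 18S rRNA control signal was 15614 to 30651 in replicates 1 and 2 and 842 to 9158 in replicates 3 and 4. Of 12735 genes, 1137 were higher and 1148 lower in replicates 3 and 4 (limma, adjusted p under 0.05). Every group held 2 arrays of each of these replicate sets. Wild-type vehicle replicate 2, wild-type estrogen replicate 2 and knockout estrogen replicate 1 had bacterial spike-in signals of 36950, 22634 and 20355 against a median of 5978, and ratios of the 3' to the 5' Actb probe set of 3.53, 2.44 and 2.07.

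**Figure D1:**
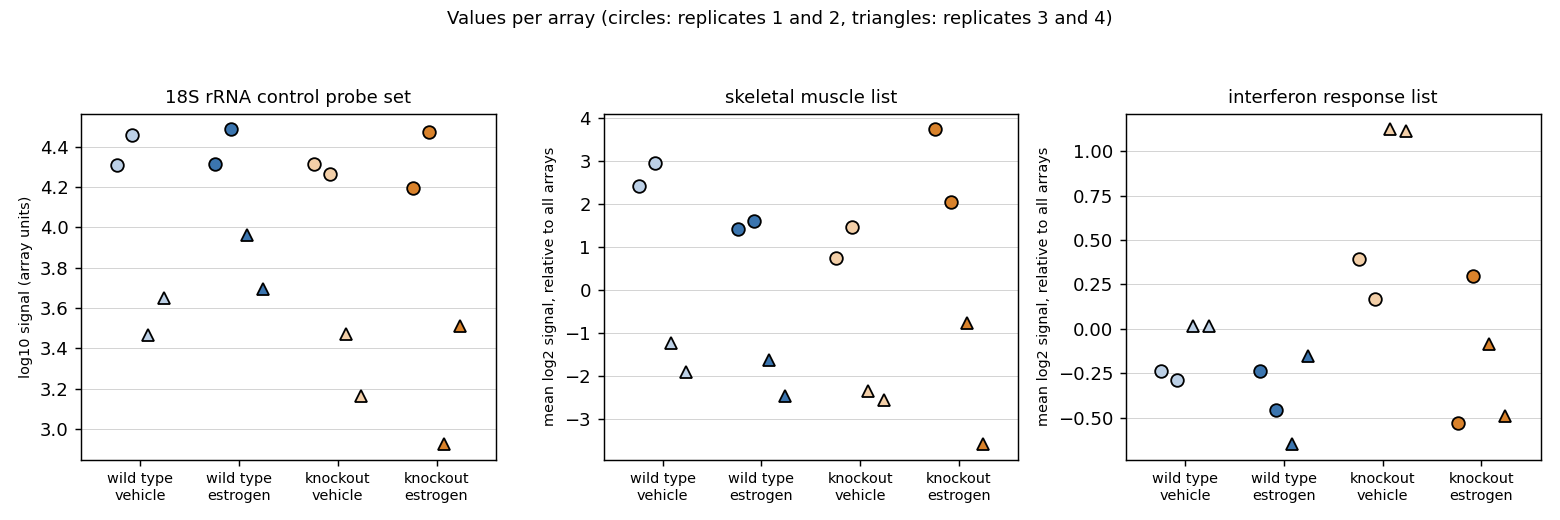
Each point is 1 of the 16 arrays, by group, with replicates 1 and 2 marked apart from replicates 3 and 4; the panels plot the 18S rRNA signal (log axis) and the mean log2 deviation of the skeletal muscle list and of the interferon response list. The 18S signal was 15614 or more in all replicates 1 and 2 and 9158 or less in all replicates 3 and 4.

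Esr1, the gene deleted in osteoclasts, had a signal of 945 ± 138 in wild type under vehicle, 507 ± 106 in wild type after estrogen, 637 ± 60.9 in the knockout under vehicle and 540 ± 149 in the knockout after estrogen. Knockout minus wild type, averaged over treatments, was −0.24 ± 0.13 on the log2 scale, which did not pass (two-sided permutation p = 0.136 over 4900 arrangements; limma p = 0.09). By limma, with no permutation test of these settings, the difference passed at −0.32 with array quality weights (p = 0.00564), −0.36 without the 3 arrays of high spike-in signal (p = 0.0135), −0.32 without knockout estrogen replicate 1 (p = 0.0148) and −0.46 within replicates 3 and 4 (p = 0.0233). It was −0.02 within replicates 1 and 2, where it did not pass. The difference was −0.55 ± 0.19 under vehicle (exact two-sided permutation p = 0.0286) and 0.07 ± 0.19 under estrogen (exact permutation p = 0.657). A second Esr1 probe set gave −0.46 for the average (permutation p = 0.0294) and the third −0.42 (permutation p = 0.0849). The probe sets may lie outside the deleted part of the gene, and other bone cells keep the receptor, so these values check neither the labels nor the deletion. Ctsk, the main collagen-degrading protease of osteoclasts, had a signal of 8729 ± 3408 in wild type under vehicle, 6940 ± 3445 in wild type after estrogen, 7440 ± 3098 in the knockout under vehicle and 9629 ± 4349 in the knockout after estrogen. Its estrogen difference was −0.38 ± 0.43 in wild type (exact permutation p = 0.543) and 0.33 ± 0.43 in the knockout (exact permutation p = 0.543), and the responses differed by 0.71 (permutation p = 0.301 over 4900 arrangements). Within replicates 1 and 2 and within replicates 3 and 4 these Ctsk values were −0.42 and −0.35 in wild type, 0.27 and 0.38 in the knockout, and 0.69 and 0.73 for the difference between the responses. Permuted within the replicate sets, a test chosen after the sets were seen to differ, Ctsk gave an exact permutation p of 0.278 in wild type and 0.278 in the knockout, where 36 arrangements allow none under 0.0556, and a permutation p of 0.0633 over 1296 arrangements for the difference (0.127 adjusted over the genes Esr1, Fasl, Fas and Ctsk). The same test gave Esr1 an exact permutation p of 0.0556 for knockout minus wild type under vehicle and a permutation p of 0.144 for the average over treatments.

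**Figure D2:**
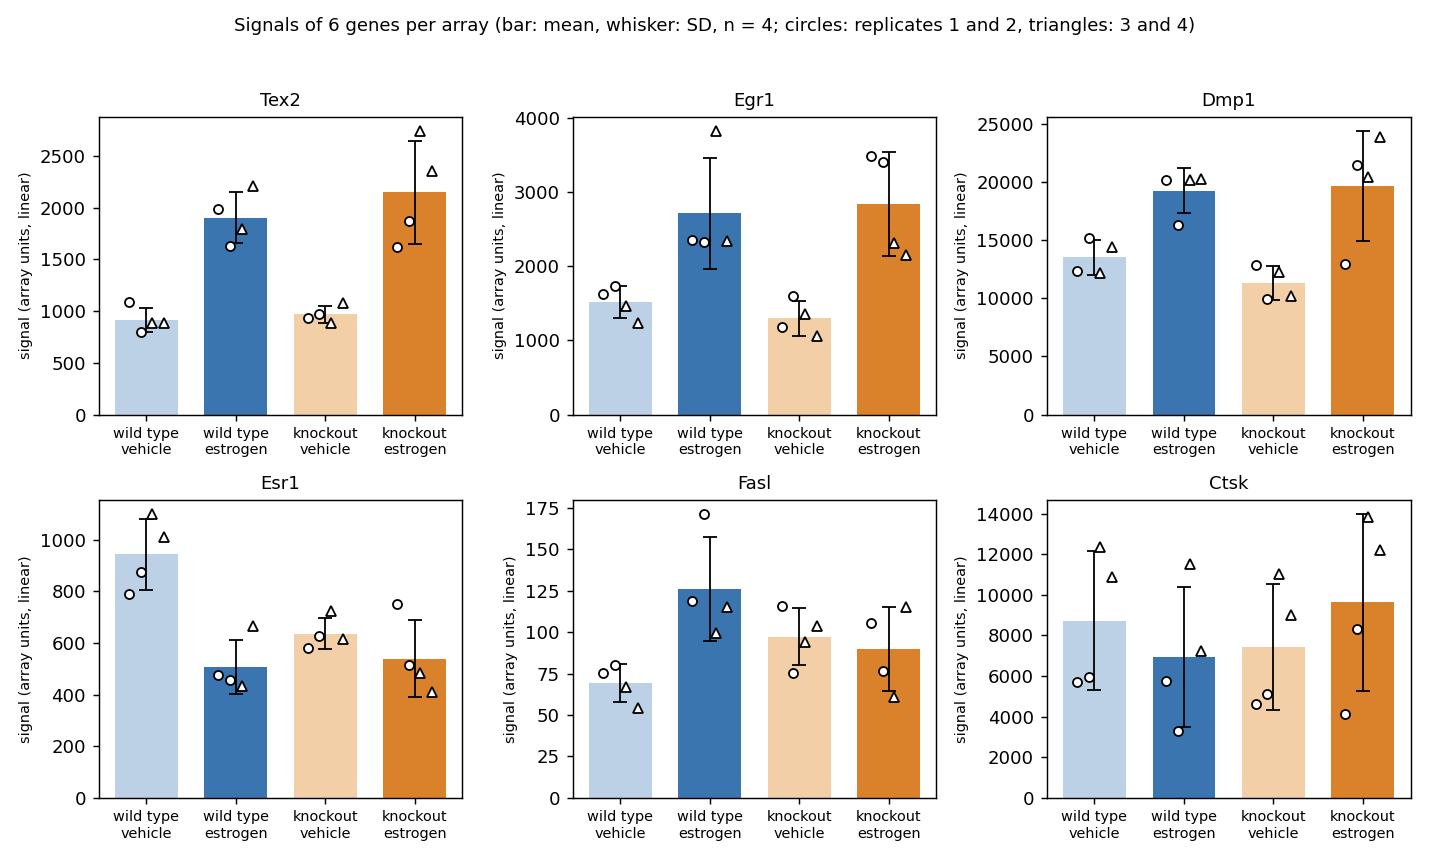
Bars give the mean signal intensity of 4 arrays per group and whiskers the SD, for Tex2, Egr1, Dmp1, Esr1, Fasl and Ctsk; points are single arrays, with replicates 1 and 2 marked apart from replicates 3 and 4. Tex2 lay between 803 and 1084 in wild type under vehicle and between 1631 and 2210 after estrogen.

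The first comparison asked what estrogen changed in wild-type femur within 4 hours. The genes with the smallest p were Tex2, Klhl13, Notch3, Antxr1 and Lrg1, and none of them passed the adjusted threshold. Tex2 (Entrez gene 21763), which encodes a lipid-transfer protein of the endoplasmic reticulum, had a signal of 915 ± 119 under vehicle and 1906 ± 249 after estrogen, a log2 difference of 1.04 ± 0.16 (limma adjusted p = 0.10). Lrg1, a secreted glycoprotein carried by neutrophils, had a signal of 2368 ± 678 under vehicle and 11367 ± 7943 after estrogen, a difference of 2.08 ± 0.39 (adjusted p = 0.123). Klhl13, an adaptor of a ubiquitin ligase, differed by −1.21 ± 0.20, the notch receptor Notch3 by −0.80 ± 0.14 and the collagen-binding receptor Antxr1 by −1.12 ± 0.20. Igf1, a growth factor for bone, went from 1940 ± 700 to 702 ± 237, a difference of −1.45 ± 0.31 (adjusted p = 0.189), and Igfbp5, which binds it, differed by −1.34 ± 0.42. Esr1 itself differed by −0.89 ± 0.19 (adjusted p = 0.189). By limma, 0 of 12735 genes passed, while 1107 had an unadjusted p under 0.05 (497 higher, 610 lower) against 637 expected by chance. The expected number assumes that genes vary independently. With the replicate set (1 and 2, or 3 and 4) as a term in the fit, chosen after the sets were seen to differ, 5 genes passed, namely Tex2 (adjusted p = 0.0161), Igf1 (adjusted p = 0.0161), Klhl13 (adjusted p = 0.0212), Ikbke and Fam167a, the last of these named after their values were seen. With array quality weights 5 genes passed, namely Tex2 (1.07, adjusted p = 0.00918), Esr1 (−1.03, adjusted p = 0.018), Antxr1 (−1.06, adjusted p = 0.0345), and Chmp1a and Upp1, named after their values were seen. Tex2 passed without knockout estrogen replicate 1, and Antxr1 and Klhl13 without knockout estrogen replicate 4.

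Of the 23 gene lists, 6 passed in wild type, with 3 higher and 3 lower. The neutrophil lineage list rose by a median log2 of 0.35, with 13 of 15 members higher (camera adjusted p = 7.58e-05; adjusted p = 0.48 with an estimated correlation). Its granule proteases Ctsg and Prtn3 differed by 1.36 ± 0.34 and 0.99 ± 0.31, and 4 members passed when adjusted over the list alone. The B lymphocyte list fell, with all 16 members lower and a median of −0.76 (adjusted p = 1.62e-05; adjusted p = 0.48 with an estimated correlation). The surrogate light chain genes Vpreb1 and Igll1, which mark B cell precursors, differed by −1.98 ± 1.07 and −1.48 ± 0.72. The glucocorticoid response list rose by a median of 0.36 with 15 of 16 members higher (adjusted p = 0.000629; adjusted p = 0.48 with an estimated correlation). Fkbp5 stood at 1.01 ± 0.23 and Ddit4 at 0.89 ± 0.49. The immediate early list rose by 0.22 with 14 of 18 members higher (adjusted p = 0.0226; adjusted p = 0.48 with an estimated correlation). Ccn1 stood at 1.10 ± 0.35 and Ier3 at 1.02 ± 0.31. The cartilage list fell by 0.74 with 16 of 17 members lower (adjusted p = 0.0132; adjusted p = 0.67 with an estimated correlation). The matrix protein genes Epyc and Matn3 stood at −1.38 ± 0.56 and −0.91 ± 0.73. The list of TGF-beta, BMP, Wnt and IGF signalling fell by 0.42 with 16 of 22 members lower (adjusted p = 0.0305; adjusted p = 0.48 with an estimated correlation).

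Adjusted over the list alone, 4 immediate early genes, 1 glucocorticoid response gene, 3 genes of TGF-beta, BMP, Wnt and IGF signalling and 0 cartilage and B lymphocyte genes passed in wild type. Among lists that did not pass, the same adjustment gave 5 estrogen response genes, 4 circadian clock genes, 1 adipocyte gene and 1 nuclear receptor gene. The circadian genes Dbp and Nr1d2 differed by −1.54 ± 0.45 and −1.17 ± 0.38, the adipocyte genes Car3 and Lpl by −1.11 and −0.83, and the nuclear receptor gene Vdr by 0.64. In replicates 1 and 2 and in replicates 3 and 4, respectively, the medians were 0.62 and 0.13 for neutrophil lineage, −0.31 and −1.08 for B lymphocyte, 0.35 and 0.55 for glucocorticoid response, 0.40 and 0.07 for immediate early, 0.14 and −1.68 for cartilage, and −0.10 and −0.34 for TGF-beta, BMP, Wnt and IGF signalling. Vpreb1 reversed likewise, at 0.22 within replicates 1 and 2 and −4.17 within replicates 3 and 4. The skeletal muscle list also passed with the replicate number as a block, as lower (adjusted p = 2e-05; adjusted p = 0.656 with an estimated correlation). The neutrophil call ended without wild-type estrogen replicate 2 (median 0.08, adjusted p = 0.0763). The cartilage call ended without wild-type vehicle replicate 3 (median −0.26, adjusted p = 0.195), vehicle replicate 4 (−0.29, 0.223) or estrogen replicate 2 (−0.45, 0.0745), and the TGF-beta, BMP, Wnt and IGF call without the same arrays (−0.19, 0.105; −0.28, 0.067; −0.27, 0.0819), each with a smaller median. The immediate early call ended without vehicle replicate 2 (median 0.27, adjusted p = 0.105), estrogen replicate 1 (0.23, 0.0873) or estrogen replicate 3 (0.19, 0.0846), where the median stayed near its value of 0.22.

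Fasl, the gene of Fas ligand (Entrez gene 14103), had a signal of 69.3 ± 11.3 in wild type under vehicle and 126 ± 31.3 after estrogen, a log2 difference of 0.72 ± 0.27. The exact two-sided permutation p was 0.0286, the smallest that 70 arrangements of 4 against 4 arrays can give, and the limma adjusted p over all genes was 0.563. In the knockout the Fasl signal was 97.2 ± 17.2 under vehicle and 89.7 ± 25.3 after estrogen, a difference of −0.12 ± 0.27 (exact permutation p = 0.686). The knockout response was lower than the wild-type response by −0.84 ± 0.39 (two-sided permutation p = 0.0208 over 4900 arrangements, 0.0833 adjusted over the 4 genes Esr1, Fasl, Fas and Ctsk; limma adjusted p = 0.767). Knockout minus wild type was 0.41 ± 0.27 for Fasl under vehicle (exact permutation p = 0.0857) and −0.44 ± 0.27 under estrogen (exact permutation p = 0.171). Fas, the receptor of this ligand, had a signal of 224 ± 147 under vehicle and 256 ± 110 after estrogen in wild type, and 281 ± 67.7 and 254 ± 175 in the knockout, with differences of 0.23 ± 0.45 (exact permutation p = 0.657) and −0.30 ± 0.45 (exact permutation p = 0.514). Fasl lay among the low signals, and in wild type its difference was 0.76 within replicates 1 and 2 and 0.69 within replicates 3 and 4. A second Fasl probe set differed by 0.25 in wild type (exact permutation p = 0.686) and 0.17 in the knockout (exact permutation p = 0.6), so its responses differed by −0.08 between the genotypes where those of the first differed by −0.84. Permuted within the replicate sets, the exact permutation p of Fasl was 0.0556 in wild type, the smallest that test allows, and for the difference between the responses the permutation p was 0.0309 over 1296 arrangements (0.123 adjusted over the 4 genes), against 0.903 for the second probe set. By limma without adjustment the wild-type difference no longer passed without vehicle replicate 4, at 0.63, or without estrogen replicate 2, at 0.58.

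The second comparison asked what estrogen changed in the femur of mice without the receptor in osteoclasts. The genes with the smallest p were Tex2, Egr1, Cd300lb, Loxl1 and Osmr, and none of them passed the adjusted threshold. Tex2 had a signal of 971 ± 82.1 under vehicle and 2148 ± 503 after estrogen, a log2 difference of 1.11 ± 0.16 (limma adjusted p = 0.0554). Egr1 (Entrez gene 13653), an immediate early transcription factor, went from 1301 ± 237 to 2839 ± 704, a difference of 1.10 ± 0.21 (adjusted p = 0.396). Cd300lb, a receptor of myeloid cells, differed by −1.13 ± 0.24, while Loxl1, which crosslinks elastin, and Osmr, the oncostatin M receptor, differed by 0.97 ± 0.21 and 0.94 ± 0.21 (adjusted p = 0.622 for each). Dmp1, a matrix protein of osteocytes, went from 11303 ± 1476 to 19656 ± 4730, a difference of 0.77 ± 0.19 (adjusted p = 0.844). By limma, 0 of 12735 genes passed, while 624 had an unadjusted p under 0.05 (211 higher, 413 lower) against 637 expected. That count was 992 with the replicate number as a block and 948 with the replicate set as a term, both above the expected number. The expected number assumes that genes vary independently, and no splits were run with these fits. Whether chance gives such counts was therefore not tested. Tex2 passed with quantile normalization (adjusted p = 0.0422), the filter at the 50th percentile (adjusted p = 0.0404) and array quality weights (1.26, adjusted p = 0.00038). It also passed with the replicate set as a term (adjusted p = 0.0232), and Tex2 and Dmp1 passed without the 3 arrays of high spike-in signal, both settings chosen after seeing the data. Tex2, Cd300lb and Ifit1bl1, the last named after its value was seen, passed without wild-type estrogen replicate 3, and Tex2 without knockout estrogen replicate 1.

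In the knockout 10 of the 23 lists passed, with 4 higher and 6 lower. The interferon response list fell by 0.91, with all 14 members lower (camera adjusted p = 5.14e-14; adjusted p = 0.0603 with an estimated correlation). The chemokine gene Cxcl10 differed by −1.82 ± 0.72 and the antiviral gene Oasl2 by −1.33 ± 0.39, and 9 interferon members passed when adjusted over the list alone. The B lymphocyte list fell by 0.62 with 14 of 16 members lower (adjusted p = 6.38e-06; adjusted p = 0.509 with an estimated correlation). Vpreb1 stood at −2.13 ± 1.07 and Igll1 at −2.04 ± 0.72. The T lymphocyte and NK cell list fell by 0.28 with 9 of 11 lower (adjusted p = 0.00496; adjusted p = 0.202 with an estimated correlation). The granzyme Gzma stood at −1.0 ± 0.34 and Cd3e at −0.97 ± 0.51. The estrogen response list rose by 0.21 with 19 of 23 higher (adjusted p = 0.000291; adjusted p = 0.0603 with an estimated correlation). The activin subunit Inhbb stood at 1.41 ± 0.43 and the matricellular protein Ccn2 at 1.04 ± 0.38. The glucocorticoid response list rose by 0.34 with 14 of 16 higher (adjusted p = 0.000424; adjusted p = 0.509 with an estimated correlation). Zbtb16 and Pdk4 both stood at 0.91, but Pdk4 reversed to −0.067 within replicates 3 and 4.

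Of the other lists in the knockout, skeletal muscle rose by 1.10 with all 20 members higher (camera adjusted p = 0.014; adjusted p = 0.643 with an estimated correlation). Actn3 stood at 1.44 ± 1.67 and Atp2a1 at 1.35 ± 1.43. The osteoblast and osteocyte list rose by 0.10 with 15 of 18 higher (adjusted p = 0.021; adjusted p = 0.509 with an estimated correlation). Tnfrsf11b, the gene of the osteoclast inhibitor osteoprotegerin, stood at 0.65 ± 0.39. The cell cycle list fell by 0.13 with 19 of 23 lower (adjusted p = 0.00822; adjusted p = 0.627 with an estimated correlation). Mcm6 stood at −0.45 and Ccnb2 at −0.39, but Ccnb2 reversed to 0.11 within replicates 3 and 4. The erythroid list fell by 0.23 with 12 of 15 lower (adjusted p = 0.02; adjusted p = 0.643 with an estimated correlation). Epb42 stood at −0.86 and Kel at −0.45. The megakaryocyte list fell by 0.16 with all 10 lower (adjusted p = 0.021; adjusted p = 0.595 with an estimated correlation). Clec1b stood at −0.40 and Gp6 at −0.37. Adjusted over the list alone, 1 osteoblast and osteocyte gene, 4 immediate early genes, 2 inflammatory cytokine genes, 1 heat shock gene and 1 gene of TGF-beta, BMP, Wnt and IGF signalling passed. Egr3 differed by 1.37 ± 0.30, Il1b by −1.38 ± 0.45, Tnf by 0.87, Dnajb1 by −0.56, Hspb1 by 0.55, Tgfb3 by 1.23 ± 0.27 and Axin2 by −0.75.

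Within replicates 1 and 2 and within replicates 3 and 4 of the knockout, the medians were −0.24 and −1.58 for interferon response, −1.10 and −0.28 for B lymphocyte, −0.26 and −0.70 for T lymphocyte and NK cell, 0.47 and 0.14 for estrogen response, and 0.67 and 0.36 for glucocorticoid response. They were 1.81 and 0.28 for skeletal muscle, 0.07 and 0.10 for osteoblast and osteocyte, −0.54 and 0.18 for cell cycle, −0.38 and −0.14 for erythroid, and −0.15 and −0.13 for megakaryocyte. The osteoclast list also passed with the replicate number as a block, as higher (adjusted p = 0.038; adjusted p = 0.59 with an estimated correlation), and so did the cartilage list, as lower (adjusted p = 0.0275; adjusted p = 0.619 with an estimated correlation). The calls of skeletal muscle, osteoblast and osteocyte, cell cycle, erythroid and megakaryocyte genes did not hold when each array was left out. At least 1 of these 5 calls ended without each of the 4 knockout vehicle and 4 knockout estrogen replicates, with adjusted p from 0.0506 to 0.983. Without knockout estrogen replicate 1 the skeletal muscle median was −0.00 (adjusted p = 0.968). The calls of skeletal muscle (median −0.0014, adjusted p = 0.993), cell cycle (0.0047, adjusted p = 0.993) and megakaryocyte genes (−0.07, adjusted p = 0.0891) also ended without the 3 arrays of high spike-in signal, and that of osteoblast and osteocyte genes with quantile normalization (0.03, adjusted p = 0.204).

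Averaged over both genotypes, estrogen raised Tex2 and Egr1. Tex2 rose by 1.08 ± 0.12 on the log2 scale, which is 2.11-fold (limma adjusted p = 0.000866), and its signals after estrogen lay above all vehicle signals in both genotypes. Egr1 rose by 0.96 ± 0.15, which is 1.94-fold (adjusted p = 0.0384), from 1514 ± 214 to 2711 ± 743 in wild type and from 1301 ± 237 to 2839 ± 704 in the knockout. The next genes did not pass, namely Esm1, an endothelial proteoglycan, at −1.07 ± 0.18 (adjusted p = 0.0699; 0.0372 with the replicate number as a block), Chmp1a, of the membrane-scission machinery, at 1.17 ± 0.23, and the osteocyte gene Dmp1 at 0.64 ± 0.13 (adjusted p = 0.301 for both). With array quality weights Esm1 (−0.97, adjusted p = 0.0218), Chmp1a (1.04, adjusted p = 0.0313), Dmp1 (0.71, adjusted p = 0.00977) and Esr1 (−0.71, adjusted p = 0.00977) passed beside Tex2 and Egr1. Esm1 also passed with quantile normalization (adjusted p = 0.041) and without wild-type estrogen replicate 1, Dmp1 without knockout estrogen replicate 1 and without the 3 arrays of high spike-in signal (0.80, adjusted p = 0.00673), and Egr3 without wild-type estrogen replicate 2. Esr1 differed by −0.57 ± 0.13 (adjusted p = 0.301; permutation p within the replicate sets 0.00772 over 1296 arrangements, 0.0309 adjusted over the 4 genes, a test chosen after seeing the data), Fasl by 0.30, Fas by −0.03 and Ctsk by −0.03. The other Esr1 probe sets gave −0.38 (permutation p within the replicate sets 0.0725) and 0.0081 (permutation p within the replicate sets 0.972) for this average. Of 12735 genes 783 had an unadjusted p under 0.05 (315 higher, 468 lower). Within replicates 1 and 2 and within replicates 3 and 4, Tex2 differed by 0.89 and 1.26 and Egr1 by 0.89 and 1.02. With the replicate number as a block 8 genes passed (5 higher, 3 lower), which besides Tex2 and Egr1 were Alas1, Aldh1a2, B4galt6, Esm1, Mcpt8 and Rgs2. With the replicate set as a term 8 passed (4 higher, 4 lower), which were Tex2, Egr1, Alas1, Esm1, Fam167a, Igf1, Ikbke and Rgs2; names among both results were given after their values were seen. Tex2 passed without any single array, while Egr1 did not pass without a variance trend (adjusted p = 0.083), without the 3 arrays of high spike-in signal (adjusted p = 0.0907), nor without any 1 of wild-type vehicle replicates 1, 2, 3 and 4, wild-type estrogen replicates 1, 3 and 4, knockout vehicle replicates 1, 3 and 4, and knockout estrogen replicates 1 and 2.

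Averaged over genotypes, 9 lists passed for estrogen, with 4 higher and 5 lower. The interferon response list fell by 0.62 with all 14 members lower (camera adjusted p = 3.67e-11; adjusted p = 0.22 with an estimated correlation), 9 of them passing when adjusted over the list alone, with Ifit3 at −0.99 ± 0.27 and Cxcl10 at −0.92 ± 0.51. The B lymphocyte list fell by 0.66 with all 16 lower (adjusted p = 3.67e-11; adjusted p = 0.22 with an estimated correlation), 8 of them passing when adjusted over the list alone, with Vpreb1 at −2.05 ± 0.75 and Igll1 at −1.76 ± 0.51. The glucocorticoid response list rose by 0.50 with 15 of 16 higher (adjusted p = 1.15e-07; adjusted p = 0.22 with an estimated correlation). The metallothionein Mt1 stood at 0.76 ± 0.19 and Pdk4 at 0.77 ± 0.66. The estrogen response list rose by 0.20 with 17 of 23 higher (adjusted p = 0.0117; adjusted p = 0.22 with an estimated correlation). Ccn1 stood at 1.06 ± 0.25 and Igf1 at −0.85 ± 0.22. The immediate early list rose by 0.16 with 11 of 18 higher (adjusted p = 0.00865; adjusted p = 0.236 with an estimated correlation), and Egr3 stood at 0.96 ± 0.21. The neutrophil lineage list rose by 0.17 with 13 of 15 higher (adjusted p = 0.00155; adjusted p = 0.355 with an estimated correlation). Ctsg stood at 0.83 ± 0.24 and Prtn3 at 0.61 ± 0.22.

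The cartilage list fell by 0.53 over both genotypes with 16 of 17 members lower (camera adjusted p = 0.000689; adjusted p = 0.569 with an estimated correlation). The collagen Col9a3 stood at −1.07 ± 0.66 and Epyc at −0.97 ± 0.40. The T lymphocyte and NK cell list fell by 0.29 with 7 of 11 lower (adjusted p = 0.0178; adjusted p = 0.236 with an estimated correlation). Cd3d stood at −1.08 ± 0.30 and Cd3e at −0.74 ± 0.36. The megakaryocyte list fell by 0.14 with all 10 lower (adjusted p = 0.00176; adjusted p = 0.27 with an estimated correlation). Gp6 stood at −0.47 ± 0.16 and Clec1b at −0.26 ± 0.12. Adjusted over the list alone, 3 glucocorticoid response, 3 estrogen response, 6 immediate early, 1 T lymphocyte and NK cell and 4 inflammatory cytokine genes passed. The same adjustment passed 1 gene each of the osteoblast, monocyte, nuclear receptor, heat shock and TGF-beta lists. Tnf differed by 1.05 ± 0.37, Il1b by −0.97 ± 0.32, the monocyte genes Cd14 and Ccr2 by 0.71 ± 0.18 and 0.45, Cthrc1 by −0.71, Vdr by 0.42, Dnajb1 by −0.43 ± 0.12, Hsph1 by −0.25 and Grem1 by 0.61. The medians of replicates 1 and 2 and of replicates 3 and 4 were −0.17 and −0.89 for interferon response, −0.68 and −0.65 for B lymphocyte, 0.44 and 0.43 for glucocorticoid response, 0.26 and 0.09 for estrogen response, 0.25 and 0.08 for immediate early, and −0.29 and −1.03 for cartilage. The erythroid list also passed with the replicate number as a block, as lower (adjusted p = 0.0169; adjusted p = 0.697 with an estimated correlation). Calls ended without wild-type vehicle replicate 1 for estrogen response (median 0.16, adjusted p = 0.0587), wild-type vehicle replicate 2 for immediate early (0.06, 0.0821), knockout estrogen replicate 1 for cartilage (−0.25, 0.118) and T lymphocyte and NK cell (−0.33, 0.104), and knockout estrogen replicate 4 for the latter (−0.24, 0.0501). Without wild-type estrogen replicate 2 the neutrophil lineage median fell from 0.17 to −0.0005 (adjusted p = 0.153), so the rise of the median depended on this array. The T lymphocyte and NK cell call also ended without the 3 arrays of high spike-in signal (median −0.27, adjusted p = 0.0854), and the neutrophil lineage call with quantile normalization (0.05, adjusted p = 0.153).

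The third comparison asked whether the estrogen response differed between the genotypes, as the response in the knockout minus that in wild type. The genes with the smallest p were Mlip, Cd274, Ephx2, Arhgap25 and Dusp7, and none of them passed the adjusted threshold (limma adjusted p = 0.631 for each). Cd274, which encodes the immune checkpoint ligand PD-L1, had a signal of 129 ± 34 under vehicle and 207 ± 31.4 after estrogen in wild type, and 202 ± 37.5 and 95.1 ± 22.9 in the knockout, an interaction of −1.63 ± 0.36. Mlip, which encodes a lamin-interacting protein of muscle, had an interaction of 1.68 ± 0.36, the epoxide hydrolase Ephx2 1.51 ± 0.34, the GTPase regulator Arhgap25 −1.08 ± 0.25 and the ERK phosphatase Dusp7 1.19 ± 0.28. By limma, 0 of 12735 genes passed, and 970 had an unadjusted p under 0.05 (495 higher, 475 lower) against 637 expected, or 1552 with the replicate number as a block. No splits were run with the block. Within replicates 1 and 2 alone 4 genes passed, namely Postn, Aspn, Itm2a and Ptn, named after their values were seen, and the matrix protein gene Postn stood at 3.51 there (adjusted p = 0.0314) against 1.81 ± 0.59 over all arrays and 0.11 within replicates 3 and 4. Across the 12735 genes, which are not independent replicates, the responses in the genotypes had a Pearson correlation of −0.093 and a Spearman correlation of −0.129, and 45.1% of genes had the same direction. Of these, 64 genes had an unadjusted p under 0.05 in both genotypes against 54.2 expected, and 42 of the 64 had the same direction.

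Of the 23 lists, 7 differed in their estrogen response between genotypes. The skeletal muscle list had a difference of 2.02 (median) between responses of opposite direction, −0.97 in wild type, where it did not pass, and 1.10 in the knockout, with all 20 members higher (camera adjusted p = 0.0155; adjusted p = 0.836 with an estimated correlation). Myl1 stood at 2.81 ± 2.21 and Casq1 at 2.67 ± 1.91, but array quality weights turned both, to −0.37 and −0.56. The interferon response list differed by −0.69 with 12 of 14 lower (adjusted p = 0.00348; adjusted p = 0.541 with an estimated correlation). Cxcl10 stood at −1.81 ± 1.01 and Usp18 at −1.19 ± 0.47. The neutrophil lineage list differed by −0.55 with 11 of 15 lower (adjusted p = 0.005; adjusted p = 0.541 with an estimated correlation). The chemokine receptor Cxcr2 stood at −1.22 ± 0.51 and Ctsg at −1.07. The cell cycle list differed by −0.29 with 19 of 23 lower (adjusted p = 0.00348; adjusted p = 0.578 with an estimated correlation). Bub1 stood at −0.69 and Mcm6 at −0.67. The estrogen response list differed by 0.33 with 16 of 23 higher (adjusted p = 0.0304; adjusted p = 0.541 with an estimated correlation). Inhbb stood at 1.78 ± 0.60 and Igfbp5 at 1.64 ± 0.60. The TGF-beta, BMP, Wnt and IGF list differed by 0.31 with 15 of 22 higher (adjusted p = 0.0304; adjusted p = 0.541 with an estimated correlation). Tgfb3 stood at 1.27 ± 0.39. The osteoblast and osteocyte list differed by 0.27 with 17 of 18 higher (adjusted p = 0.0171; adjusted p = 0.541 with an estimated correlation). Tnfrsf11b stood at 0.99.

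For the difference between the responses, 1 circadian clock gene passed when adjusted over the list alone, and Dbp stood at 1.62 ± 0.64 and Nr1d2 at 1.59 ± 0.54. By replicate set (1 and 2, then 3 and 4), the medians were 3.09 and 0.91 for skeletal muscle, −0.23 and −1.11 for interferon response, −0.48 and −0.09 for neutrophil lineage, and −0.74 and 0.13 for cell cycle. They were 0.36 and 0.14 for estrogen response, 0.25 and 0.11 for TGF-beta, BMP, Wnt and IGF signalling, and 0.17 and 0.33 for osteoblast and osteocyte. With the replicate number as a block the adipocyte list (adjusted p = 0.0378) and the circadian clock list (0.0399) also passed as higher, and Fas and apoptosis as lower (0.0399); adjusted p = 0.564 with an estimated correlation for each of these. The interferon response call held without any single array. The other 6 calls each ended without at least 1 array, and every array but knockout vehicle replicate 2 and knockout estrogen replicate 4 ended at least 1 of them, with adjusted p from 0.05 to 0.3. Neutrophil lineage ended without wild-type estrogen replicate 2 (median −0.33, adjusted p = 0.156) and cell cycle without knockout estrogen replicate 1 (median −0.10, adjusted p = 0.0772). Without the 3 arrays of high spike-in signal the skeletal muscle (median 0.80, adjusted p = 0.469) and cell cycle (−0.09, adjusted p = 0.164) calls ended.

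The fourth comparison set knockout against wild type under vehicle. The genes with the smallest p were Aldh1a2, Klhl13, Fam71b, Gch1 and Serpinb6e, and none of them passed the adjusted threshold. Aldh1a2 (Entrez gene 19378), which makes retinoic acid, had a signal of 563 ± 64.5 in wild type and 158 ± 56.9 in the knockout, a log2 difference of −1.80 ± 0.31 (limma adjusted p = 0.331). Klhl13 differed by −0.91 ± 0.20, Fam71b by 1.63 ± 0.39, Gch1, the first enzyme of tetrahydrobiopterin synthesis, by 0.81 ± 0.20, and the serpin gene Serpinb6e by −1.67 ± 0.41 (adjusted p = 0.952 for each). By limma, 0 of 12735 genes passed, and 459 had an unadjusted p under 0.05 (275 higher, 184 lower) against 637 expected. That count was 750 with the replicate number as a block and 830 with the replicate set as a term, above the expected number. No splits were run with these fits, so whether chance gives such counts was not tested. With array quality weights 1 gene passed, Aldh1a2, at −1.71 (adjusted p = 0.0272).

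Of the 23 lists, 5 differed between knockout and wild type under vehicle. The interferon response list was higher in the knockout by a median of 0.79 with all 14 members higher (camera adjusted p = 1.04e-12; adjusted p = 0.148 with an estimated correlation), and 5 members passed when adjusted over the list alone. The antiviral gene Ifit1 had a signal of 423 ± 71.6 in wild type and 1280 ± 553 in the knockout, a difference of 1.47 ± 0.39, and Cxcl10 differed by 1.4 ± 0.72. The cell cycle list was higher by 0.28 with 22 of 23 higher (adjusted p = 2.16e-05; adjusted p = 0.436 with an estimated correlation). Bub1 and Top2a both stood at 0.43. The erythroid list was higher by 0.48 with 13 of 15 higher (adjusted p = 0.00135; adjusted p = 0.62 with an estimated correlation). Epb42 stood at 0.81 and the transcription factor Tal1 at 0.64. The skeletal muscle list was lower by −1.36 with 19 of 20 lower (adjusted p = 0.00349; adjusted p = 0.865 with an estimated correlation). Myl1 stood at −1.89 ± 1.56 and Mylpf at −1.76 ± 1.63, but array quality weights turned Mylpf to 0.030. The adipocyte list was lower by −0.68 with 6 of 8 lower (adjusted p = 0.0107; adjusted p = 0.436 with an estimated correlation). Car3 stood at −1.08 and the adipokine Retn at −1.02. In replicates 1 and 2 and in replicates 3 and 4, respectively, the medians were 0.37 and 1.16 for interferon response, 0.34 and 0.06 for cell cycle, 0.59 and 0.31 for erythroid, −1.63 and −0.99 for skeletal muscle, and −1.09 and −0.19 for adipocyte. The skeletal muscle call ended without wild-type vehicle replicate 1 (median −0.73, adjusted p = 0.209) or 2 (−0.65, 0.278) or knockout vehicle replicate 3 (−0.87, 0.217) or 4 (−0.72, 0.166), or without the 3 arrays of high spike-in signal (median −0.65, adjusted p = 0.28), the adipocyte call without wild-type vehicle replicate 1 (−0.50, 0.121) or knockout vehicle replicate 3 (−0.67, 0.0557), and the erythroid call without wild-type vehicle replicate 3 (0.32, 0.179).

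The fifth comparison set knockout against wild type after estrogen. The genes with the smallest p were Col5a1, Bin3, Arhgap15, Cdk14 and Ptgfrn, and none of them passed (limma adjusted p = 0.607 for each). Col5a1, a chain of fibrillar collagen, had a signal of 1841 ± 716 in wild type and 4307 ± 563 in the knockout, a log2 difference of 1.31 ± 0.26. Cdk14, a cyclin-dependent kinase, differed by 1.14 ± 0.25, Ptgfrn by 0.93 ± 0.21, Bin3 by −0.83 ± 0.17 and the GTPase regulator Arhgap15 by −0.80 ± 0.16. The neutrophil lineage list was lower in the knockout by −0.45 with all 15 members lower (camera adjusted p = 4.97e-05; adjusted p = 0.646 with an estimated correlation). Ctsg stood at −0.78 ± 0.34 and Prtn3 at −0.76 ± 0.31. It was the only one of the 23 lists to pass, and 1 circadian clock gene passed when adjusted over the list alone, with Nr1d2 at 1.00 ± 0.38 and Dbp at 0.87 ± 0.45. By limma, 0 of 12735 genes passed, and 859 had an unadjusted p under 0.05 (457 higher, 402 lower) against 637 expected. With the replicate number as a block 5 lists passed, now with osteoblast and osteocyte (adjusted p = 0.0349), skeletal muscle (0.000763), circadian clock (0.0349) and TGF-beta, BMP, Wnt and IGF signalling (0.0349), all higher, and 5 passed with the replicate set as a term. With an estimated correlation under the block none of these passed (adjusted p = 0.816 for osteoblast and osteocyte, circadian clock and TGF-beta, BMP, Wnt and IGF signalling, and adjusted p = 0.89 for skeletal muscle). The neutrophil median was −0.76 within replicates 1 and 2 and −0.11 within replicates 3 and 4, and without wild-type estrogen replicate 2 it was −0.24 and did not pass (adjusted p = 0.112), nor did it without the 3 arrays of high spike-in signal (−0.14, adjusted p = 0.062), while 2, 3, 2 and 4 lists passed without wild-type estrogen replicate 3 and knockout estrogen replicates 1, 3 and 4.

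Averaged over treatments, no gene passed between knockout and wild type, and Aldh1a2 came closest at −1.41 ± 0.22 (limma adjusted p = 0.102). Cilp2, a cartilage matrix protein gene, differed by 1.37 ± 0.28, Serpinb6e by −1.38 ± 0.29, the casein gene Csn3 by −0.94 ± 0.21 and Fam71b by 1.18 ± 0.27. The interferon response list was higher in the knockout by 0.50 with all 14 members higher (camera adjusted p = 4.53e-11; adjusted p = 0.224 with an estimated correlation). Ifit1 stood at 0.98 ± 0.28 and Ifit3 at 0.83 ± 0.27. Of its members 3 passed when adjusted over the list alone. The erythroid list was higher by 0.34 with 13 of 15 higher (adjusted p = 0.00103; adjusted p = 0.975 with an estimated correlation). Ank1 stood at 0.59 and Hemgn at 0.48. The neutrophil lineage list was lower by −0.24 with 14 of 15 lower (adjusted p = 0.00135; adjusted p = 0.975 with an estimated correlation). Prtn3 stood at −0.38 and S100a9 at −0.30. The cell cycle list was higher by 0.09 with 21 of 23 higher (adjusted p = 0.0281; adjusted p = 0.975 with an estimated correlation). The replication helicase genes Mcm4 and Mcm2 both stood at 0.32. By limma, 0 of 12735 genes passed and 386 had an unadjusted p under 0.05 (238 higher, 148 lower). Aldh1a2 passed with the replicate set as a term (adjusted p = 0.0164), and 1 gene, Aldh1a2, passed without wild-type estrogen replicate 2 or knockout estrogen replicate 3. The medians of replicates 1 and 2 and of replicates 3 and 4 were 0.35 and 0.54 for interferon response, 0.25 and 0.32 for erythroid, −0.45 and −0.01 for neutrophil lineage, and 0.01 and 0.16 for cell cycle. The skeletal muscle (adjusted p = 0.000487) and adipocyte (0.00918) lists also passed with the replicate number as a block, as lower (adjusted p = 0.899 and adjusted p = 0.815 with an estimated correlation). The neutrophil call ended without wild-type estrogen replicate 2 (median −0.07, adjusted p = 0.268), without the 3 arrays of high spike-in signal (median −0.02, adjusted p = 0.824) and with quantile normalization (−0.06, adjusted p = 0.403), and the erythroid call without wild-type estrogen replicate 3 (median 0.12, adjusted p = 0.154). The cell cycle call ended without wild-type vehicle replicate 3 (0.129), wild-type estrogen replicate 3 (0.154), knockout vehicle replicate 1 (0.0955) or 2 (0.161), or knockout estrogen replicate 2 (0.0749), 3 (0.136) or 4 (0.447), with medians from 0.06 to 0.09.

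Of the 161 tests of 23 lists in 7 comparisons, 42 passed, and 0 passed with camera's estimated correlation or with fry; in the passing tests the median, the mean and the test had the same sign. The lists that passed in no comparison of the main fit were osteoclast, monocyte and macrophage, endothelium, nuclear receptors and coregulators for steroids, Fas and apoptosis, circadian clock, heat shock and inflammatory cytokines. The osteoclast list had medians of 0.08 for estrogen in wild type, 0.14 for estrogen in the knockout, −0.12 for knockout minus wild type under vehicle and −0.04 under estrogen, and its smallest adjusted p was 0.134. In the same order the medians were 0.01, 0.06, −0.09 and 0.02 for monocyte and macrophage, 0.04, 0.10, −0.04 and 0.01 for endothelium, and −0.15, 0.08, −0.03 and 0.14 for heat shock. They were 0.21, −0.11, 0.13 and −0.16 for Fas and apoptosis and −0.10, 0.16, −0.08 and 0.36 for circadian clock. The steroid receptor list had −0.10, 0.07, 0.00 and 0.07, and the inflammatory cytokine list −0.03, 0.21, 0.08 and −0.01. The inflammatory cytokine list is one where signs differed, with a mean of −0.02 and a test direction of lower beside its median of 0.21 in the knockout. The Fas and apoptosis list came closest to passing in the difference between the responses, at −0.26 (adjusted p = 0.0519), and it passed there with the replicate number as a block (adjusted p = 0.0399; adjusted p = 0.564 with an estimated correlation) and with the replicate set as a term (adjusted p = 0.0408; adjusted p = 0.481 with an estimated correlation).

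**Figure D3:**
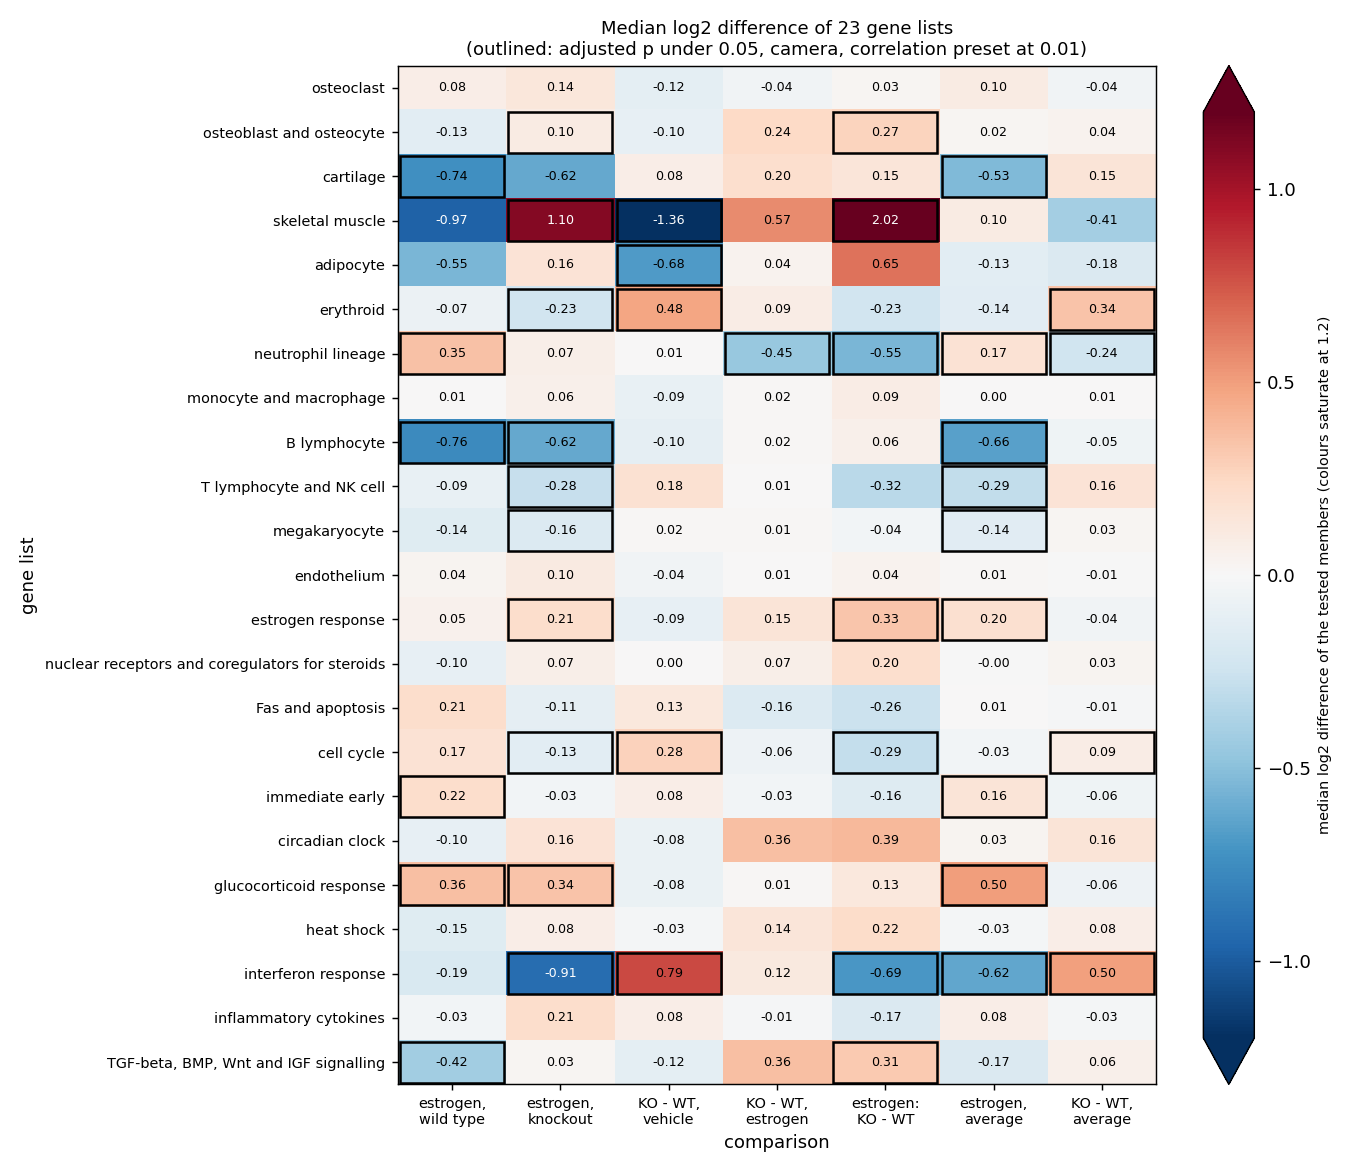
Each cell gives the median log2 difference of 1 of the 23 gene lists in 1 of the 7 comparisons, and an outline marks a list that passed camera with the preset correlation. The B lymphocyte list stood at −0.76 for estrogen in wild type and −0.62 in the knockout, and the interferon response list at 0.79 for knockout minus wild type under vehicle.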

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

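The tests of explanations in this part were chosen after the results were seen, except the set of random matched lists, which was fixed before its result was seen. The Fasl response to estrogen differed between the genotypes by −0.84 (log2, knockout minus wild type; permutation p = 0.0208 over 4900 arrangements, 0.0833 adjusted over 4 genes), and was 0.72 in wild type and −0.12 in the knockout. A second Fasl probe set of like mean level gave responses of 0.25 and 0.17, which differed by −0.08, and permuted within the replicate sets the permutation p was 0.0309 over 1296 arrangements for the first probe set (0.123 adjusted) and 0.903 for the second. A rise of T lymphocyte and NK cell genes as large as that of the first Fasl probe set was argued against. The mean of their list in wild type was −0.11 (95% interval −0.53 to 0.30), and the first Fasl probe set exceeded it by 0.84 (0.13 to 1.54). The second probe set was not set against the list, and a rise in only a part of these cells was not tested. A need for estrogen receptor alpha in osteoclasts stays open, since the difference between the responses restates what was observed and does not test it. Noise of 1 probe set at a low signal also stays open, because that second probe set differed by 0.25 in wild type with an interval of −0.70 to 1.19 that holds both no change and the change of the first probe set.

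Interferon response genes were higher in the knockout under vehicle, with a mean of 0.82 over the list (95% interval 0.29 to 1.35; exact permutation p = 0.0286, 0.526 adjusted over the lists), and their estrogen response differed between the genotypes by −0.69. The 4 leukocyte lists rose less than the interferon list in the knockout. The largest mean difference among the 4 lists was 0.28, for T lymphocytes and NK cells (−0.13 to 0.70), and the interferon list exceeded it by 0.54 (0.21 to 0.87). The interferon list was followed up because of its difference, so this excess was partly built in. A change in only a part of the leukocytes was not tested, so blood or marrow leukocytes as the source stay open. One array deciding the difference was argued against, since the median stayed between 0.59 and 1.04 when each of the 8 arrays was left out (highest adjusted p = 2.92e-08 by camera with the preset correlation; with all arrays the list does not pass with an estimated correlation, adjusted p = 0.148). Loss of estrogen receptor alpha in osteoclasts might be the source, but it stays open, because the median difference between knockout and wild type after estrogen was 0.12 (adjusted p = 0.347). The mean list scores under vehicle were 0.39, 0.17, 1.12 and 1.12 in knockout replicates 1, 2, 3 and 4 and −0.24, −0.29, 0.02 and 0.02 in wild type.

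Skeletal muscle genes were lower in replicates 3 and 4 of all groups by a median of −4.04. All 20 members were lower there in all 4 groups, by −2.95 to −6.27, which restates the pattern, so skeletal muscle left on the bone stays an open and untested candidate source of these transcripts. Skeletal muscle as the whole difference between the replicate sets was argued against, because it would dilute all other cells alike, while the osteoclast list shifted by 0.67 and the erythroid list by −0.39, a difference of 1.06 (exact permutation p = 0.000155 over 12870 arrangements). A labelling or hybridization effect on all genes of like mean expression was argued against. Of 1000 random lists so matched, 0 were as low (lowest median −0.31). Other such effects stay open. No biological explanation was tested, since every group lies in both replicate sets.

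The following lists had estrogen responses that differed between the genotypes by camera with the preset correlation, as knockout minus wild type; none of them passed with an estimated correlation. The median difference was 2.02 for skeletal muscle, 0.27 for osteoblast and osteocyte, 0.33 for estrogen response, 0.31 for TGF-beta, BMP, Wnt and IGF signalling, −0.55 for neutrophil lineage and −0.29 for cell cycle.

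One array lay far from the other 3 of its group in 27 of 484 groups of arrays, over 98 named genes and 23 list scores, where chance gives about 1 in 20, which is 24.2. Wild-type vehicle replicate 1 had signals of 26.8 for Cxcl10 (others 177 to 218) and 1493 for Dnajb1 (2149 to 2234). Wild-type vehicle replicate 2 had 480 for Bub1 (909 to 961), 78.9 for Cd274 (138 to 151), 440.5 for Dusp7 (371 to 378) and 1461 for Fkbp5 (892 to 954), and a T lymphocyte and NK cell score of −0.39 (0.08 to 0.13). Wild-type vehicle replicate 4 had 414 for Inhbb (321 to 323). Wild-type estrogen replicate 2 had 16328 for Dmp1 (20165 to 20225), 1177 for Retn (356 to 415) and a neutrophil lineage score of 1.09 (0.02 to 0.14). Wild-type estrogen replicate 3 had the erythroid genes Ank1 at 559 (2477 to 3332), Hemgn at 2306 (8853 to 9020) and Kel at 695 (1973 to 2377), and an erythroid score of −1.24 (0.09 to 0.25). The same array had Egr1 at 3826 (2326 to 2350), Igfbp5 at 779 (2291 to 2738) and Klhl13 at 397 (483 to 498).

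Knockout vehicle replicate 1 had a Bin3 signal of 2534 (others 2204 to 2241), knockout vehicle replicate 3 a Grem1 signal of 434 (214 to 226) and knockout vehicle replicate 4 a Col9a3 signal of 1497 (2378 to 2612). Knockout estrogen replicate 1 had Axin2 at 115 (195 to 216) and knockout estrogen replicate 4 had Klhl13 at 381 (608 to 645). Knockout estrogen replicate 2 had Egr3 at 352 (573 to 628), Hemgn at 13096 (8417 to 8947), Ier3 at 1403 (580 to 615) and a monocyte and macrophage score of −0.14 (0.11 to 0.14).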

How the results depend on the processing

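The replicate set (1 and 2, or 3 and 4) as a term, each set alone, every named probe set with that term, and all settings without the 3 arrays of highest spike-in signal were chosen after seeing the data. Over the 170 results for named genes, 5086 of 5194 alternatives kept the direction and the side of the threshold, 17 lost the call, 40 gained one and 51 reversed; over the 42 passing lists, 845 of 1050 kept both, 199 lost the call and 6 reversed. Of the losses among lists, 77 came from leaving out 1 array. Among the named genes only Tex2 and Egr1 passed in the main fit, for estrogen averaged over genotypes. Most alternatives that kept a named-gene result therefore kept a gene that did not pass. All 17 losses fell on Tex2 and Egr1, and 12 of them came from leaving out 1 array, each for Egr1. Most of the reversals concern Fas, Fasl, Ctsk and Esr1 in comparisons where they did not pass. Low signals and the number of arrays limit Fasl, and its second probe set gave 0.25 in wild type and 0.17 in the knockout. Except where a reason stands in the sentence, the cause was not tested.

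With quantile normalization 1 gene, Tex2, passed for estrogen in the knockout, and Fasl for knockout minus wild type averaged over treatments (the genotype average) was 0.0069; 3 list calls ended, those of osteoblast and osteocyte for estrogen in the knockout and of neutrophil lineage for the estrogen and genotype averages. With the filter at the 50th percentile Tex2 passed as the 1 gene for estrogen in the knockout, where fewer genes were tested. With eBayes without trend 1 gene passed for the estrogen average. With array quality weights 5 genes passed for estrogen in wild type, 1 in the knockout, 1 for knockout minus wild type under vehicle and 6 for the estrogen average; Mylpf under vehicle was 0.030, Esr1 for knockout minus wild type under estrogen −0.0029, the interactions of Myl1 and Casq1 −0.37 and −0.56, Fas 0.041 for the estrogen average and −0.013 for the genotype average, and Esr1 for the genotype average −0.32. With every named probe set tested 1 gene, Tex2, passed for the estrogen average. With the batch term (the replicate set) added 4 passed for estrogen in wild type, 2 in the knockout, 1 for knockout minus wild type under estrogen and 1 for the genotype average. The second Esr1 probe set gave −0.46 for the genotype average.

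With the replicate number as a block 8 genes passed for the estrogen average and 5 lists for knockout minus wild type under estrogen; the block ended no call of a named gene in the comparison that names it and gained that of Esm1 alone there, while Aldh1a2, named for the genotype differences, passed for the estrogen average; it ended no call of a list, and moved no other count of passing genes or lists by more than 1.5 times. The lists gained under the block did not pass with an estimated correlation. The batch term gave 5 genes for estrogen in wild type, 1 in the knockout, 8 for the estrogen average and 1 for the genotype average, and 5 lists for knockout minus wild type under estrogen. Without the 3 arrays 8 of the 42 list calls ended and 1 reversed; 2 genes passed for estrogen in the knockout and 5 lists for knockout minus wild type under estrogen; the skeletal muscle list for estrogen in the knockout was −0.0014, Esr1 for knockout minus wild type under estrogen −0.14, Ctsk for the estrogen average 0.23, and Esr1, Fasl and Fas for the genotype average −0.36, 0.045 and −0.0092. Without the 3 arrays and with the batch term 5 list calls ended and 1 reversed; 3 genes passed for estrogen in the knockout and 12 for the estrogen average, and 9 and 6 lists for knockout minus wild type under vehicle and under estrogen. In that setting Fasl in wild type was 0.64, the cell cycle list for estrogen in the knockout 0.019, Esr1 for knockout minus wild type under estrogen −0.14, Ctsk for the estrogen average 0.16, and Esr1, Fasl and Fas for the genotype average −0.35, 0.042 and −0.067.

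In replicates 1 and 2 alone, with fewer arrays, 0 genes passed for the estrogen average by limma and 4 for the interaction, and 7 lists for knockout minus wild type under estrogen. Estrogen in wild type gave 0.76 for Fasl, 0.22 for Vpreb1 and 0.14 for the cartilage list, estrogen in the knockout 0.043 for Esr1 and 0.19 for Fas, and the estrogen average 0.25 for Fas. In replicates 3 and 4 alone 12 lists passed for knockout minus wild type under vehicle, 6 under estrogen and 10 for the genotype average, 65 over all comparisons. Fasl in wild type was 0.69, Ccnb2, Pdk4 and the cell cycle list for estrogen in the knockout 0.11, −0.067 and 0.18, and Esr1 for knockout minus wild type under estrogen −0.26. The cell cycle list for the interaction was 0.13, Ctsk for the estrogen average 0.018, and Esr1 and Fasl for the genotype average −0.46 and 0.15. With an estimated correlation in camera, and with fry, 0 lists passed in each of the 7 comparisons, against 42 in all.

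Leaving out each array in turn gave 1 to 3 genes for the estrogen average, 0 to 2 for estrogen in wild type, 0 to 3 in the knockout and 0 to 1 for the genotype average. It gave 6 to 11 lists for estrogen in the knockout, 0 to 4 for knockout minus wild type under estrogen, 3 to 9 for the interaction and 3 to 7 for the genotype average. Fasl ranged from 0.58 to 0.82 for estrogen in wild type, −0.24 to 0.023 in the knockout and −0.073 to 0.055 for the genotype average. Fas ranged from −0.0076 to 0.60 for estrogen in wild type, −0.23 to 0.15 for the estrogen average, −0.47 to 0.19 for knockout minus wild type under estrogen and −0.0068 to 0.37 for the genotype average. Esr1 ranged from −0.10 to 0.20 for knockout minus wild type under estrogen and −0.32 to −0.17 for the genotype average, Ctsk from −0.17 to 0.15 for the estrogen average and −0.041 to 0.30 for the genotype average, and the skeletal muscle list for estrogen in the knockout from −0.0014 to 2.36.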

Other observations

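Of the tests in this part, the comparisons of splits were fixed before their results were seen, and the values of single Greb1 and Pgr probe sets were chosen after seeing the data. Greb1, a classical target of estrogen receptors, had a probe set, not the one of highest mean, with a signal of 58.6 ± 8.02 (SD, n = 4) under vehicle and 220 ± 66.2 after estrogen in wild type, a log2 difference of 1.63 (exact two-sided permutation p = 0.0286). In the knockout the same probe set had 66.0 ± 20.3 under vehicle and 174 ± 84.6 after estrogen, a difference of 1.16 (exact permutation p = 0.0286). The other 3 Greb1 probe sets differed by −0.02, 0.24 and −0.76 in wild type and by 0.69, 1.31 and 0.96 in the knockout, so their directions disagree in wild type. Pgr, the progesterone receptor gene, differed by 0.61 in wild type (exact permutation p = 0.114) and 0.09 in the knockout (exact permutation p = 0.8).

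For estrogen averaged over genotypes, 3 of 100 splits of the arrays, the real one included, gave as many genes passing the adjusted threshold as the real 2. This share of 0.03 was the only one under 0.05 among the counts of genes and lists of all comparisons. It was not corrected for the number of counts, so it does not exclude chance. The 783 genes at an unadjusted p under 0.05 were reached by 26 of 100 splits (highest other 2285). Leaving out 1 array gave 1 to 3 passing genes. The highest of the other splits gave 160 genes and divided the arrays along the replicate sets, which points to a structure of the samples. With the replicate number as a block 8 genes passed, and within replicates 1 and 2 and within replicates 3 and 4 Tex2 differed by 0.89 and 1.26. Among 100 further splits that part the replicate numbers as the real one does, 2, the real one included, gave as many genes as the real split, and the highest other gave 3, while 12 reached the 783 genes of the unadjusted threshold (highest other 1239).

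The other counts of genes were all 0 by limma, which every split reaches, so the splits say nothing about them. These were all 35 splits for estrogen in wild type (highest other 3), estrogen in the knockout (0), knockout against wild type under vehicle (1) and under estrogen (6, by the split along the replicate sets), and all 100 splits for the interaction (2) and the genotype average (381, along the replicate sets). For lists, as many came from 11 of 35 splits for estrogen in wild type (6 real, highest other 9), 2 of 35 in the knockout (10 and 10), 17 of 35 for knockout against wild type under vehicle (5 and 9) and 35 of 35 under estrogen (1 and 11), and over these splits, which include those along the replicate sets, chance could not be excluded. The same holds for 41 of 100 splits for the interaction (7 and 14), 9 of 100 for the estrogen average (9 and 11) and 79 of 100 for the genotype average (4 and 13). At an unadjusted p under 0.05 the split along the replicate sets gave 2812 genes for the wild-type arrays and 1554 for the knockout arrays, against 1107 and 624 for the real splits. Among the 8 splits that part the pairs, which are too few for a share under 0.05, the highest others gave 936 and 460 genes, for knockout against wild type 263 under vehicle (real 459) and 1693 under estrogen (real 859). Among the 6 such splits of all arrays by treatment, also too few, the highest others gave 1126 for the interaction (real 970) and 1239 for the estrogen average (real 783), and among 9 by genotype, too few as well, 984 for the genotype average (real 386). For lists the highest others of the 8 gave 5 in wild type against 6 for the real split, 9 in the knockout against 10, 8 for knockout against wild type under vehicle against 5, and 11 under estrogen against 1. Over the 100 further splits that part the replicate numbers, the estrogen average reached its 9 lists in 6, with a highest other of 12. The splits that keep pairs together reached higher counts of genes at the unadjusted threshold.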
